A study of Homo sapiens with 10 samples.

How the data were processed

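RNA sequencing was analysed for 10 libraries of KYSE-410, an established human oesophageal squamous cell carcinoma line. The libraries came from 1 control colony, transfected with an empty vector, and from 4 clones (D4, G4, G10 and H3) edited with the Cas9 nickase to knock out SHIP2, the protein encoded by INPPL1. Each of the 5 groups had 2 libraries, made with the Ovation Solo kit from total RNA. The deposited values were CPM (counts-per-million of gene-assigned reads) per the file headers, 1 column per library. The authors' processing notes list STAR 2.5.3a and HTSeq with the hg38 genome; they do not state the strand setting, the annotation release or any filter. No column of values in the deposited table was left unused.

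The table held 58302 genes, of which 58039 were matched by Ensembl identifier in GENCODE release 29 for positions and gene types. Every library summed to 1000001 CPM after rounding. The deposited CPM values were whole multiples of a common step, as if reads had been scaled to a common total (20009089 to 20015835 after rounding up) in each library. Reads were estimated by undoing that scaling, which explained 99.81% to 99.91% of the values above 0 within a misfit of at most 2 scaled units. By this estimate depth ran from 9653835 to 14253437 gene-assigned reads, and 25060 to 26991 genes lay above 0 in a library. A count of 0 allows up to 3 reads, or 0.21 to 0.311 CPM depending on the library. These floors cover counting error only, since the reads carry no molecular identifiers as far as the labels state. On simulated libraries put through the same scaling, the step returned 100% of the read counts, which tests only that it inverts that scaling.

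The analysis had been laid out for raw counts. Because the deposited unit was CPM, edgeR was not used, and the fallback written into the plan took its place. That fallback was limma (3.58.1, with a trend and robust moderation, in R 4.3.3) on log2(CPM + 1). Genes with at least 1 CPM in at least 2 libraries were kept, which left 17664. The model had 1 coefficient per group, 5 residual degrees of freedom and no covariate. The main contrast was the mean of the 4 clones minus the control. Each clone was also compared with the control and with the mean of the other 3 clones, and an F test compared the 4 clones with each other. P values were adjusted by the Benjamini-Hochberg method at 0.05. The error in these tests is the spread between 2 libraries of a group, so they compare these clones with this control colony. Fits that take the clone as the unit of replication were therefore run as alternatives. Genes changed the same way in all 4 clones were the overlap of the 4 single-clone lists. That overlap was set beside data simulated with no effect and beside the count with each other group as the reference.

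The lists, the rule for named genes, the contrasts and most of the alternative settings were fixed before the data were examined. The rule named the 12 largest rises and 12 largest falls among genes that passed for the mean of the 4 clones and in each clone. It also required every knock-out library on 1 side of both control libraries and a mean of at least 5 CPM. For each clone, the 3 largest rises and falls against the other 3 clones were named, and for each list up to 4 members with the largest change. INPPL1, PLK1, AKT1, AKT2, PIK3CA, EGFR, TP63 and SOX2 were among the genes named whatever their change. Some genes that the rule names are not reported here. The 38 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The 2 lists with fewer than 5 tested genes were left without a test.

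The alternatives, carried over from the count fit to limma, were median-of-ratios size factors, no filter, a minimum mean of 5 CPM, limma-voom on the estimated reads, a pseudocount of 0.1 and the replicate number as a block. Each library and each knock-out clone was also left out in turn. The DESeq2 Wald test was not run, since the deposited values were not counts. Medians over windows of 50 neighbouring tested genes along each chromosome were examined after the data had been seen, and so was the alternative that subtracts them. Only genes with a mean of at least 5 CPM made up the windows. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9. The fit was tested on simulated data with seeded changes. Of genes seeded with a 1.5-fold change 62.7% were recovered for the mean of the 4 clones and 17.9% in all 4 clones. At 2-fold these shares were 98.5% and 89.6%, and at 4-fold 100% and 98.5%. Among 16657 unchanged genes 4 were called for the mean and 0 in all 4 clones. The seeded list passed, as did 1 other list, which held a seeded gene, and the 9 windows of a seeded chromosome shift were all found.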

Results

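The 10 RNA libraries of KYSE-410 formed 5 groups of 2, namely 1 control colony and the SHIP2 knock-out clones D4, G4, G10 and H3. SHIP2 is a phosphoinositide phosphatase that acts on the lipid products of PI3K. Depth, estimated by undoing the scaling of the deposited CPM values, was 11196315 and 13077590 reads in the control libraries and 10198890 and 9653835 in those of D4. It was 10293887 and 10158218 reads in G4, 13214427 and 14253437 in G10, and 11960936 and 13319016 in H3. Libraries of 1 group correlated at r = 0.9911 to 0.9962 across genes, which are not independent replicates. The spread between the 2 libraries of G10 was 10.6 times the variance that counting alone would give, against 2.03 to 3.35 times in the other groups.

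The first question was how the transcript of the targeted gene stood in the edited clones. INPPL1 (ENSG00000165458, chromosome 11, 72223701 to 72239105 on hg38) fell in every clone, and by very different amounts. The control stood at 144.88 CPM ± 6.95 (SD, n = 2) and G10 at 9.49 CPM ± 0 (SD, n = 2), which is 6.55% of the control. G4 stood at 64.87 CPM ± 0.7 (SD, n = 2), or 44.8% of the control. D4, at 88.44 CPM ± 6.84, and H3, at 86.71 CPM ± 1.95 (SD, n = 2 each), kept 61% and 59.9%. The log2 fold change by limma was −3.80 ± 0.08 in G10 (SE, adjusted p = 1.37e-14), −1.15 in G4 (adjusted p = 1.01e-07), −0.71 in D4 (adjusted p = 3.32e-06) and −0.73 in H3 (adjusted p = 1.8e-06). INPPL1 lies in a window of neighbouring genes, 69048897 to 75018893 of chromosome 11, whose median was −0.49 in H3, so part of the H3 change is shared with its neighbours. That median was −0.13 in D4, −0.09 in G4 and −0.17 in G10. The 4 clones differed from each other (adjusted p = 1.46e-13, limma F test). A small edit can remove a protein without lowering its mRNA, and SHIP2 protein was not analysed here.

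**Figure D1:**
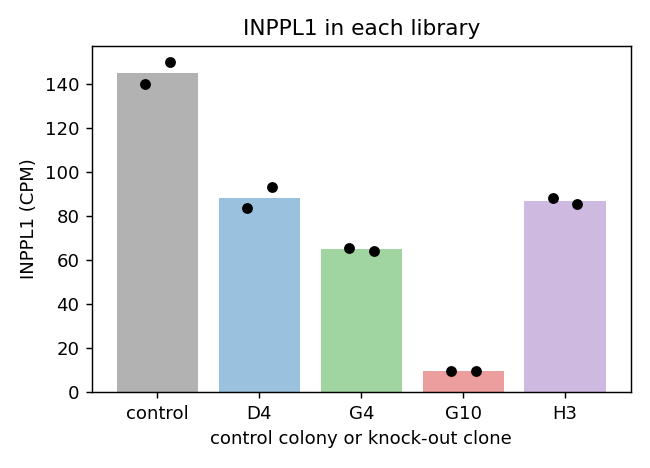
INPPL1 level in CPM (y axis) in the control colony and the 4 knock-out clones (x axis), with bars at the group mean and points for the 2 libraries of each group. G10 stands at 9.49 CPM and the control at 144.88 CPM, with D4, G4 and H3 between them.

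The main comparison asked what the 4 clones share against the control colony. The 12 rises and 12 falls named first passed in each clone, and of these 24 genes all but BTBD16 changed least in G4. KRT6A (ENSG00000205420, chromosome 12, 52487174 to 52493257), a keratin of activated and cancerous squamous epithelium, fell from 909.03 CPM ± 13.96 in the control to 232.29 CPM in G4 and to 5.4 to 11.32 CPM in the other clones. Its log2 fold change, the mean of the 4 clones' differences from the control on the log2(CPM + 1) scale, was −5.55 ± 0.10 (SE, adjusted p = 4.11e-13, limma), with n = 2 libraries per group as in all that follows. KRT6A has near-identical paralogs, KRT6B and KRT6C, and reads shared between them were not separated here.

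SERPINB2, an inhibitor of urokinase, followed among the losses and fell from 250.91 CPM to 69.52 CPM in G4 and 1.02 CPM in D4 (mean log2 fold change −4.34). Its neighbour SERPINB10 fell alike (−4.18), but the annotated genes overlap, and how reads in the shared stretch were assigned is not known. CPT1A, which carries long-chain fatty acids into mitochondria, fell from 222.83 CPM to 1.9 CPM in H3, 5.12 CPM in G10 and 10.02 CPM in D4, but only to 156.78 CPM in G4. The interstitial collagenase MMP1 (−3.92) and the stromelysin MMP10 (−2.67) fell, as did LY6D, a surface marker of squamous cells (−3.80), and the inflammasome sensor NLRP1 (−3.35). CHL1, a neural cell adhesion molecule, fell from 31.45 CPM to between 0.35 and 3.5 CPM in the 4 clones (−3.33 ± 0.12, SE). GALNT18, a glycosyltransferase of mucin-type sugars (−3.10), TTYH2, a membrane protein of the tweety family (−2.75), and the non-coding APCDD1L-AS1 (−2.77) completed the set. The adjusted p values of these 12 losses ran from 2.71e-14 to 9.7e-09.

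Among the gains, CNTNAP2, a neurexin family adhesion protein, rose from 0.97 CPM ± 0.18 to a mean of 10.55 CPM over the clones (log2 fold change 2.48 ± 0.11, SE, adjusted p = 1.62e-10). SCNN1A, a subunit of the epithelial sodium channel, rose from 15.12 CPM to 163.52 CPM in D4, 87.04 CPM in H3, 39.5 CPM in G10 and 29.29 CPM in G4 (mean 2.01). The growth factor TGFB2 rose (1.94), and PLAT, the tissue plasminogen activator, rose from 1.02 to 9.39 CPM (2.18). P3H2, a prolyl hydroxylase of collagen (1.78), and the laminin chain gene LAMA1 (1.77) rose. NAV2, a neuron navigator protein, rose (2.01) together with its antisense transcript NAV2-AS1 (1.89), which lies within NAV2 and whose reads are not separable from those of NAV2 without the strand setting. BTBD16 (2.28), METTL7A (1.99), PLAC8 (1.91) and PCED1B (1.80) rose as well. All 12 gains passed in each clone, with adjusted p values over the 4 clones from 1.91e-12 to 2.25e-06.

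**Figure D2:**
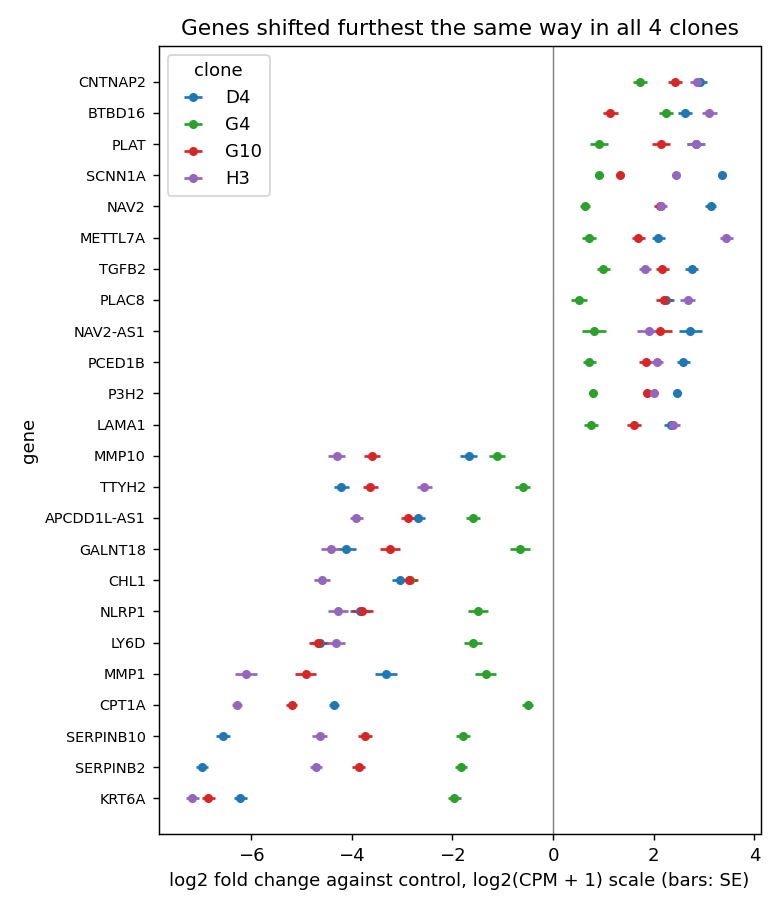
Log2 fold change against the control on the log2(CPM + 1) scale (x axis) of the 24 named genes (y axis), with 1 point per clone and bars of 1 SE. KRT6A lies between −7.16 and −1.96, and the points of G4 lie nearest to 0 for all genes except BTBD16.

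Over all 17664 genes tested, limma called 3215 higher and 3890 lower in the mean of the 4 clones, of which 173 and 301 changed at least 2-fold. In all 4 clones alike, 497 genes rose and 689 fell, against 14.3 and 29.2 if the 4 lists were independent and at most 1 in 50 simulations with no effect. With median-of-ratios size factors there were 3543 higher and 3470 lower for the mean, and 621 and 579 in all 4 clones, so which direction holds more genes depends on the scaling. All 4 lists share the same 2 control libraries, which cannot be split further, so the excess over independent lists includes whatever that sharing adds. At least 2-fold in each clone, 7 rose and 53 fell. More genes passed that size against every other group with D4 (88) or H3 (155) as the reference. Fewer did with G4 (49) or G10 (40). The 7105 genes called for the mean became 4503 without control replicate 1 and 4633 without control replicate 2, and the 1186 shared genes became 702 and 738. With the clone as the unit of replication, limma called 0 genes from clone means (693 at an unadjusted p under 0.05) and 16 with the clone as a random block (1262 unadjusted). A fit of 2 groups that ignored the clone and counted each library as a replicate called 306 (3160 unadjusted).

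Genes of the pathway that SHIP2 belongs to moved little as a group. Of 37 tested phosphoinositide phosphatases and kinases, 8 rose and 7 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.767), with a median log2 fold change of −0.01 and a mean of 0.04. PIK3R3, a regulatory subunit of PI3K, rose in all 4 clones (0.88) and the inositol phosphatase INPP5J rose on average (1.02). PIK3CA, the catalytic subunit often mutated in carcinomas, fell by 0.58 (adjusted p = 0.000131). AKT1, a kinase activated by PI3K lipids, did not pass (0.04, adjusted p = 0.638). AKT2 fell by 0.23 (adjusted p = 0.00401), a call that was lost without control replicate 2 (−0.16, adjusted p = 0.134). With window medians subtracted AKT2 stood at 0.05 (adjusted p = 0.539), so its fall goes with that of its neighbours on chromosome 19. Targets of FOXO factors, which AKT restrains, went both ways, 9 up and 7 down of 26, or 9 and 8 adjusted over the list alone (adjusted p = 0.767). Their median was −0.01 while camera ranked them upward. TXNIP, a thioredoxin inhibitor, fell (−1.23), SESN3 fell (−1.58) and CAT, which encodes catalase, rose (0.91). Endocytosis genes and SHIP2 partners showed 7 rises and 10 falls of 39, also over the list alone (adjusted p = 0.625). FCHSD2 and CBL were down by a log2 fold change of −0.59 and −0.51, and SNX9 rose in all 4 clones (0.51). FCHSD2 and CBL fell most in H3 (−1.13 and −1.07), where their windows of chromosome 11 each had a median of −0.49.

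The basal squamous group had the lowest camera adjusted p of the lists, which depends on list size as well as on the shift. Of its 30 genes 22 fell and 4 rose, the same counts as adjusted over the list alone, and 12 fell in all 4 clones. Its median was −0.71 over the clones, from −0.32 in G4 to −1.07 in H3 (camera adjusted p = 1.27e-09; adjusted p = 0.0624 with an estimated correlation). KRT6C (−3.09), KRT6B (−2.56) and COL17A1, a hemidesmosome collagen (−2.38), were the largest after KRT6A. COL17A1 stayed at 278.74 CPM in G4 against 289.81 CPM in the control, with 27.68 to 36.15 CPM in the other clones. The squamous master regulator TP63 fell by 0.54 over the clones (adjusted p = 2.06e-06) but did not pass in G4 (0.12, adjusted p = 0.247). SOX2, its partner in squamous carcinomas, fell from 7.4 CPM to 0.35 to 1.25 CPM in D4, G10 and H3 and stood at 8.2 CPM in G4 (0.13, adjusted p = 0.645). PIK3CA, SOX2 and TP63 lie on the long arm of chromosome 3, where neighbouring genes also had lower medians in D4, G10 and H3. With window medians subtracted, the fall of PIK3CA did not pass (−0.16, adjusted p = 0.211) and that of TP63 shrank to −0.16 (adjusted p = 0.0399), while SOX2 stood at −1.26 (adjusted p = 4.72e-06). Unfolded protein response and ATF4 genes, which handle misfolded proteins and amino acid shortage, fell in 23 of 32 and rose in 2, also over the list alone. Their median was −0.42 (camera adjusted p = 1.03e-06; adjusted p = 0.0624 with an estimated correlation). ASNS, the asparagine synthetase (−1.35), TRIB3 (−1.18), CHAC1 (−1.15) and SESN2 (−1.11) led them, and 10 members fell in all 4 clones. Replication-dependent histone genes fell in 8 of 9 tested, or in all 9 adjusted over the list alone, with a median of −0.93 (camera adjusted p = 4.54e-05; adjusted p = 0.0624 with an estimated correlation). HIST2H2BE (−1.27) and HIST1H2AC (−1.06) were the largest. Only 9 of 42 listed symbols were tested, in part because the list holds old and new symbols of the same genes.

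Sterol and fatty acid synthesis lists passed over the 4 clones together. Of 25 cholesterol synthesis and uptake genes 19 rose and 1 fell, also over the list alone, with a median of 0.66 (camera adjusted p = 4.02e-08; adjusted p = 0.106 with an estimated correlation). The medians were 1.00 in D4, 1.06 in H3 and 0.54 in G4, but −0.01 in G10. LSS, the lanosterol synthase (1.27), MVK, the mevalonate kinase (1.12), and HMGCS1, an early enzyme of the pathway (1.06), were among the largest. Fatty acid synthesis genes rose in 13 of 24 and fell in 3, also over the list alone, with a median of 0.30 (camera adjusted p = 0.000225; adjusted p = 0.0624 with an estimated correlation). ACSS2, which makes acetyl-CoA from acetate (1.18), and LPIN1, a phosphatidate phosphatase (0.97), were examples. Mitochondrially encoded genes rose in 12 of 15, also over the list alone, with a median of 0.24 (camera adjusted p = 0.000262; adjusted p = 0.479 with an estimated correlation). MT-CYB had the largest change (0.50), and the median in G10 was −0.07. Nuclear genes of oxidative phosphorylation rose in 13 of 37 and fell in 6, or 16 and 6 adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.0326; adjusted p = 0.475 with an estimated correlation). This call was lost without control replicate 2 (adjusted p = 0.0664). Hypoxia and glycolysis genes went both ways, 11 up and 10 down of 35, or 12 and 10 over the list alone (adjusted p = 0.767, median 0.01, mean −0.01). NDRG1, a hypoxia-responsive gene, fell (−2.22) while CA9, a carbonic anhydrase, rose (1.22).

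Mitotic genes rose by small amounts. Of 36 G2/M genes 29 rose and 1 fell, or 30 and 2 adjusted over the list alone, with a median of 0.30 (camera adjusted p = 2.9e-08; adjusted p = 0.242 with an estimated correlation). BUB1, a checkpoint kinase (0.70), and UBE2C, a ubiquitin-conjugating enzyme of mitotic exit (0.63), were the largest. PLK1 did not pass (0.04, adjusted p = 0.61) and passed in opposite directions in D4 (−0.32, adjusted p = 0.00355) and G4 (0.48, adjusted p = 0.000305). Without clone D4 it passed (0.16, adjusted p = 0.049), as it did with window medians subtracted (0.42, adjusted p = 6.38e-05). G1/S and DNA replication genes rose in 14 of 33 and fell in 3, also over the list alone, with a median of 0.11 (camera adjusted p = 0.0324; adjusted p = 0.479 with an estimated correlation). This call was lost without control replicate 1 (adjusted p = 0.0717). GINS1 (0.40) and RRM1, a subunit of ribonucleotide reductase (0.36), rose. Cytosolic ribosomal protein genes rose in 17 of 44 and fell in 3, or 18 and 3 adjusted over the list alone, with a median of 0.08 (camera adjusted p = 0.0237; adjusted p = 0.604 with an estimated correlation). MYC targets of ribosome biogenesis rose in 6 and fell in 7 of 29, or 7 and 7 over the list alone (adjusted p = 0.866). ODC1, which starts polyamine synthesis, fell (−0.81). Of 26 p53 targets 5 rose and 9 fell, or 6 and 10 adjusted over the list alone (adjusted p = 0.559). CDKN1A, the cell cycle inhibitor p21, fell in all 4 clones (−0.93), as did ZMAT3 (−0.93). Apoptosis regulators rose in 7 and fell in 13 of 33, or 8 and 13 over the list alone (adjusted p = 0.569), with the caspase inhibitor BIRC2 down in all 4 clones (−0.64).

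Growth factor and ERK genes fell on average, most in H3. Receptor tyrosine kinases and EGF family ligands fell in 14 of 30 and rose in 3, or 14 and 4 adjusted over the list alone, with a median of −0.18 (camera adjusted p = 0.0306; adjusted p = 0.173 with an estimated correlation). EGFR, the main receptor of the family in squamous cells, went from 571.35 CPM ± 22.12 to 308.43 CPM in G10 and 240.4 CPM in H3 (mean −0.64, adjusted p = 2.63e-07). In D4 it did not pass (−0.12, adjusted p = 0.184). The ligand genes HBEGF (−1.45) and AREG (−1.25) and the receptor genes EPHB3 (−1.16) and FGFR3 (−0.97) fell on average. Outputs of the ERK pathway fell in 10 of 24 and rose in 4, also over the list alone, with a median of −0.13, −0.63 in H3 and 0.24 in G4 (camera adjusted p = 0.0306; adjusted p = 0.242 with an estimated correlation). The phosphatase gene DUSP5 (−1.21) and the feedback inhibitor gene SPRY2 (−0.92) were examples. Immediate early and heat shock genes, which respond to handling of cells, fell in 10 of 23 and rose in 0, also over the list alone, with a median of −0.18 (camera adjusted p = 0.0326; adjusted p = 0.475 with an estimated correlation). HSPA6, an inducible heat shock protein, was the largest (−1.32), and the call was lost without control replicate 2 (adjusted p = 0.0664).

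Interferon and antigen presentation genes rose. Type I interferon response genes rose in 16 of 30 and fell in 3, or 17 and 4 adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.000861; adjusted p = 0.207 with an estimated correlation). BST2, a membrane tether of viruses, rose from 0.3 CPM to 68.01 CPM in D4, 32.43 CPM in G10 and 75.65 CPM in H3, and stood at 0.4 CPM in G4. IFIT3 rose in all 4 clones (0.93). Antigen presentation genes rose in 13 of 18 and fell in 2, also over the list alone, with a median of 0.30 (camera adjusted p = 0.000861; adjusted p = 0.101 with an estimated correlation). The immunoproteasome genes PSMB9 (0.91) and PSMB8 (0.73) rose in all 4 clones. The list had its largest median in G4 (0.45), where 2 windows of chromosome 6, from 29722775 to 33276510, were shifted by 0.33 and 0.40, the second of which holds PSMB8 and PSMB9. With window medians subtracted both still passed (PSMB9 0.79 and PSMB8 0.61). Of 23 NF-kappaB and inflammatory genes 5 rose and 8 fell, or 5 and 9 over the list alone (adjusted p = 0.559), with the cytokine gene IL1A down (−1.74).

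The calls for matrix metalloproteinase, squamous differentiation, mesenchymal and fibroblast genes were each lost when 1 library was left out. Matrix metalloproteinases and plasminogen system genes fell in 14 of 24 and rose in 5, or 15 and 5 adjusted over the list alone, with a median of −0.25 (camera adjusted p = 0.0423; adjusted p = 0.267 with an estimated correlation). Apart from MMP1, MMP10 and PLAT, the collagenase MMP13 was the largest (−1.09). The call was lost without control replicate 1 (adjusted p = 0.0717), D4 replicate 1 (0.0523) or G4 replicate 1 (0.0576). Squamous differentiation and cornification genes fell in 13 of 30 and rose in 6, or 14 and 6 adjusted over the list alone, with a median of −0.25 (camera adjusted p = 0.0458; adjusted p = 0.208 with an estimated correlation). SERPINB13 (−2.15), the transcription factor GRHL3 (−2.01) and FLG, which encodes filaggrin (−1.53), followed LY6D. That call was lost without control replicate 2 (adjusted p = 0.0683), D4 replicate 1 (0.0654), D4 replicate 2 (0.0538), G10 replicate 1 (0.0576) or G10 replicate 2 (0.0591). Mesenchymal and EMT genes rose in 13 of 31 and fell in 10, also over the list alone, with a median of 0.17 (camera adjusted p = 0.0353; adjusted p = 0.359 with an estimated correlation), a call lost without D4 replicate 1 (adjusted p = 0.0523). The intermediate filament gene VIM rose in all 4 clones (1.37), WNT5A rose on average (1.83) and TNC, a matrix glycoprotein, fell (−1.32). Beside them, 3 of 5 tested fibroblast markers rose, also over the list alone (median 0.23, camera adjusted p = 0.033; adjusted p = 0.242 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.0645) and with no filter on low values (adjusted p = 0.107). LUM, a small proteoglycan (2.55), and C1R, a complement protease (0.78), rose on average, though LUM did not pass in G4 (0.08, adjusted p = 0.633). The third, FBLN1 (0.23), fell in G10 (−0.83), stood at −0.03 without clone D4 (adjusted p = 0.786) and did not pass without control replicate 1 (0.12, adjusted p = 0.381) or without clone H3 (0.06, adjusted p = 0.609).

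Of the remaining groups only the genes near INPPL1, given last, passed. Columnar and glandular epithelial markers rose in 4 of 10 and fell in 1, also over the list alone (median 0.15, camera adjusted p = 0.0538). This call passed without control replicate 1 (adjusted p = 0.0493), control replicate 2 (0.036) or H3 replicate 2 (0.046). The simple-epithelium keratin genes KRT18 (1.08) and KRT8 (0.97) rose in all 4 clones, KRT8 least in G4 (0.34, adjusted p = 0.0486). Both lie in a window of chromosome 12 with a median of 0.27 to 0.44 in the clones, and with window medians subtracted KRT18 stood at 0.76 and KRT8 at 0.65 (adjusted p = 2.7e-09 and 0.000359). Of 3 tested immune markers 1 fell and of 4 endothelial markers 1 rose, also over the list alone, too few for a test. Epithelial junction and polarity genes rose in 7 and fell in 12 of 34, also over the list alone (adjusted p = 0.559), with OCLN, which encodes occludin, at −0.81. Integrins and focal adhesion genes rose in 11 and fell in 11 of 35, also over the list alone (adjusted p = 0.871, median 0, mean −0.07 and ranked upward by camera). TNS1, a tensin of adhesion sites, fell in all 4 clones (−2.50), and the kinase gene SRC rose in all 4 (0.87). YAP/TAZ targets rose in 9 and fell in 8 of 25, also over the list alone (adjusted p = 0.526), and AXL, a receptor kinase, rose on average (0.70). TGF-beta and SMAD targets rose in 10 and fell in 11 of 26, or 11 and 11 over the list alone (adjusted p = 0.981, median −0.06, mean 0.02), with the inhibitor ID2 down (−1.32). WNT targets rose in 3 and fell in 4 of 15, also over the list alone (adjusted p = 0.565), with TCF7 at −0.84. Notch genes rose in 6 and fell in 8 of 21, or 6 and 10 over the list alone (adjusted p = 0.559), with HES2 (−1.41) and NRARP (−1.37) down in all 4 clones. NRF2 targets rose in 11 and fell in 16 of 32, or 11 and 17 over the list alone (adjusted p = 0.24), with a median of 0.33 in G4 and −0.80 in G10. Genes near INPPL1 on chromosome 11 passed, with 13 of 27 down and 2 up, or 15 and 3 adjusted over the list alone (median −0.18, −0.45 in H3, camera adjusted p = 0.0306; adjusted p = 0.237 with an estimated correlation). The chloride channel gene ANO1 had the largest change (−1.02).

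**Figure D3:**
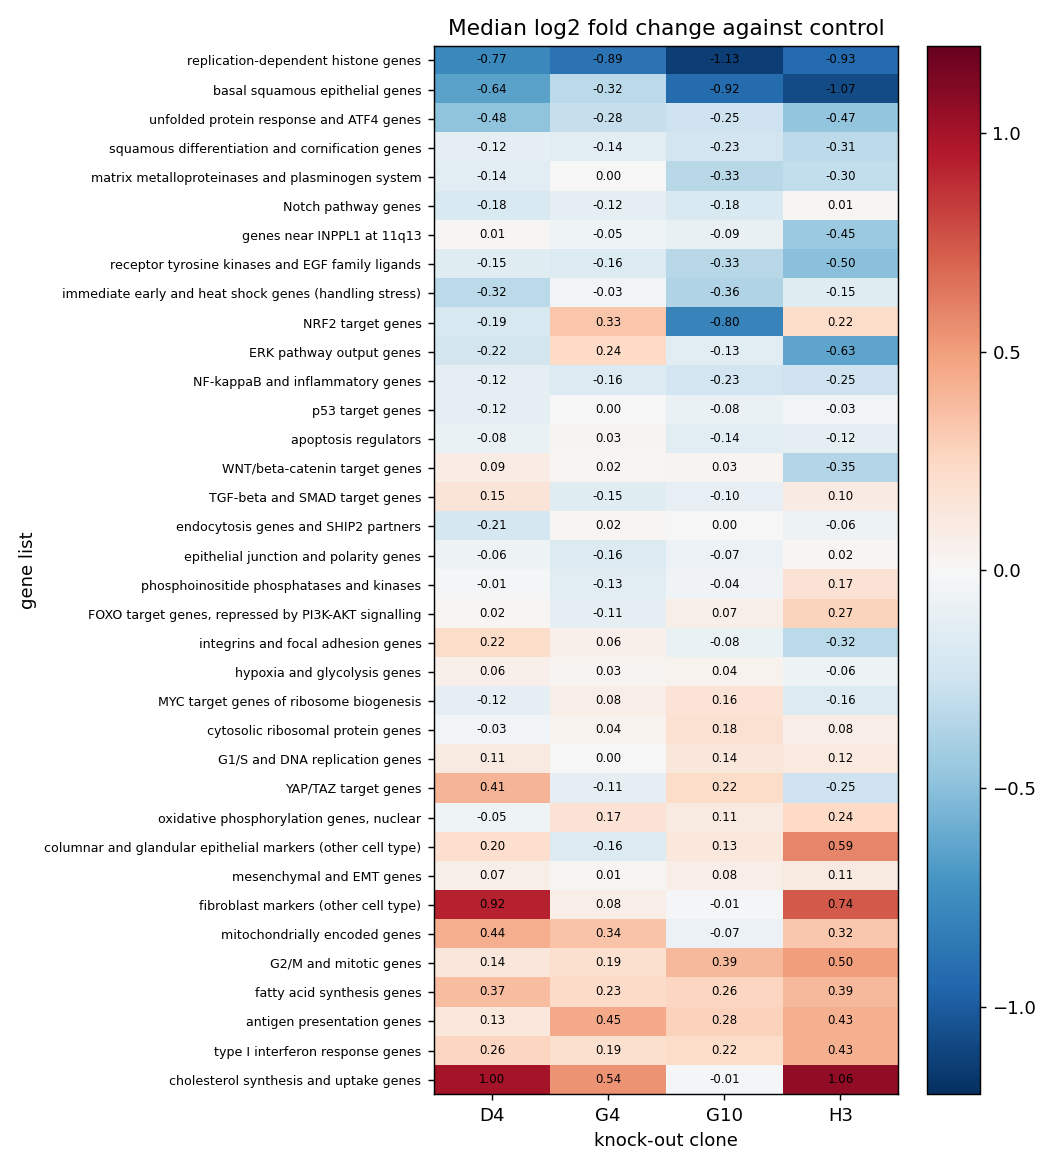
Median log2 fold change against the control (colour and printed value) of each of the 36 gene lists tested (y axis) in each of the 4 clones (x axis). Replication-dependent histone genes run from −1.13 to −0.77, and cholesterol genes are at 1.06 in H3 and −0.01 in G10.

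In 20 of the 36 tested lists the camera call passed, and in 0 with an estimated correlation, where the lowest adjusted p was 0.0624. Self-contained tests with fry called 32 lists, and these do not compare a list with other genes. By the mean log2(CPM + 1) of a list's genes, the control lay above all 4 clones in 12 lists, below all 4 in 6 and within their range in 18. Any 1 of 5 groups lies outside the range of the others in some lists by chance alone. The list tests take their error from libraries of the same clone, and only 1 control colony was sampled.

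The next comparison was of the knock-out clones with each other and with the control. The clones differed widely. By the limma F test 11889 genes (67.3%) differed among the 4, and 1576 were called in opposite directions against the control in at least 2 clones. Against the control D4 had 3090 genes higher and 4196 lower, G4 1922 and 2905, G10 3152 and 3379, and H3 4221 and 3912. With median-of-ratios size factors the balance turned in D4 (3648 and 3513) and G4 (2529 and 2360) and kept its direction in G10 (3199 and 3343) and H3 (4096 and 4025). The G4 count of 4827 became 3044 without control replicate 1, 3213 without control replicate 2, 2852 without G4 replicate 1 and 3071 without G4 replicate 2. Control and G4 were the pair with the fewest differing genes, followed by D4 and G10 with 5205, and control and H3 the pair with the most, 8133. With another group as the reference, the genes shifted the same way in all others numbered 1115 for D4, 1146 for G4, 919 for G10 and 2180 for H3, against 1186 for the control.

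**Figure D4:**
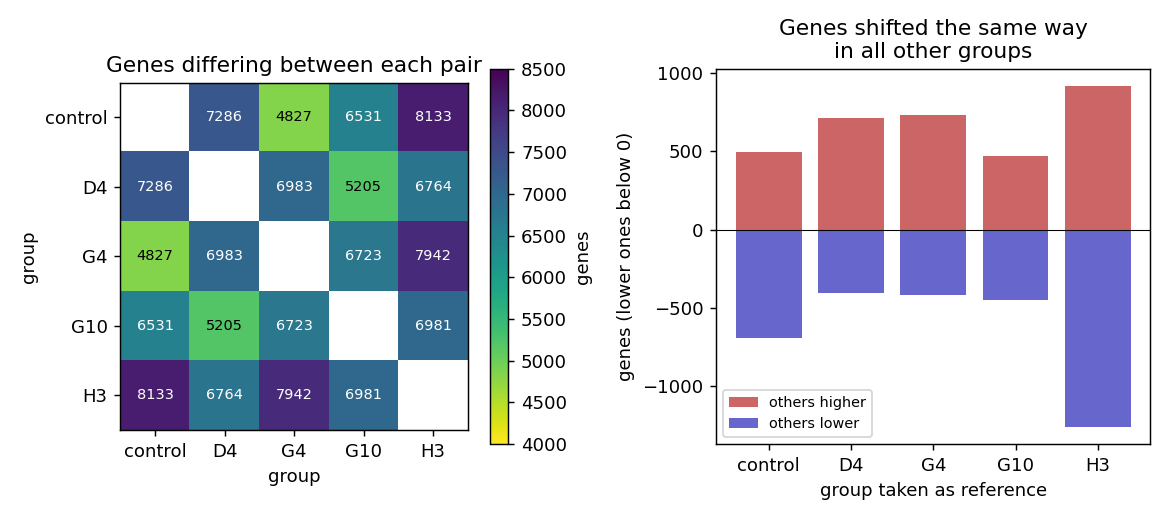
Left, genes differing between each pair of groups (colour and printed count). Right, genes higher (above 0) and lower (below 0) in all other groups when the group on the x axis is the reference. The control gives 497 and 689 genes, and H3 gives 919 and 1261.

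Each clone had its own outstanding genes against the other 3 clones. D4 had lost PNMA5, which lies near the end of the long arm of chromosome X, from 265.45 CPM in the control to 0.12 CPM (log2 fold change −7.66 ± 0.06 against the other clones, SE, adjusted p = 5.21e-21). It had gained RASGRP1, an activator of RAS, at 57.34 CPM against 0.35 to 27.6 CPM in the other clones, and UPK1B, a bladder epithelium tetraspanin (3.19). SRGN, a proteoglycan of secretory granules (3.03), stood at 26.83 CPM in D4, 15.39 CPM in G4 and 9.89 CPM in the control. Its difference also reflects low levels in G10 (0.85 CPM) and H3 (0.3 CPM). BTBD11 was lower in D4 (−3.36), as was SERPINB2 (−3.49). G4 held KRT6A (4.78), CPT1A (4.77) and the imprinted gene MEST (4.74) above the other clones, with MEST at 90.93 CPM against 102.13 CPM in the control. BST2 (−5.33) and RASGRP1 (−3.72) were lower in G4 than in the others. G10 was lower in AKR1B10 (−3.79), AKR1C3 (−3.45) and AKR1C1 (−3.43), which encode enzymes of carbonyl and steroid metabolism. CACNG7, a calcium channel subunit (2.58), TMEM200A (2.48) and PNMA5 (2.60) were higher in G10, the last because its mean over the others includes D4. H3 had gained the carboxylesterase gene CES1, at 58.81 CPM against 0.4 to 7.2 CPM, MCF2L (3.04) and ATOH8 (2.92). It had lost WNT7A, a secreted signal (−3.49). The cadherin gene CDH6 (−3.50) was lowest in H3 at 2.05 CPM, but D4 (7.4 CPM) and G10 (36.4 CPM) also lay below the control (93.31 CPM). In G4 CDH6 stood at 129.81 CPM. ME3, a mitochondrial malic enzyme, was listed at 0 CPM in both H3 libraries and at 7.62 to 10.67 CPM in the other clones. In total 5913 genes in D4, 7567 in G4, 5856 in G10 and 7707 in H3 passed for this difference by limma, with adjusted p values of the named genes of 2.9e-09 or lower.

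Runs of neighbouring genes moved together in 1 clone or in several, a pattern examined after the values were seen. Between 18.1% and 24% of the 254 windows in a clone had a median beyond the shuffled orders. Of these windows 72 were shifted in 1 clone, 28 in 2, 20 in 3 and 4 in all 4, each time in the same direction. The 4 shared by all were 2 windows of chromosome 6, from 130013699 to 170584692, at 0.31 to 0.49, and 1 of chromosome 12, from 50392383 to 53939643, at 0.27 to 0.44, with 1 of chromosome 19, from 23827162 to 35754519, at −0.35 to −0.44. In D4 the last windows of chromosome X, from 147911951 to the end, had medians of −0.95 and −0.96. In G4 the median over the 427 genes of chromosome 14 with a mean of at least 5 CPM was −0.51. The lowest window of that chromosome, 24114195 to 35317474, was at −0.81. In G10 the window from 10797050 to 30586872 of chromosome 11, which holds NAV2, was at 0.69, with 0.55 in D4, 0.53 in H3 and −0.16 in G4. In H3 the window from 19067599 to 27364778 of chromosome 16, which holds PLK1, was at −0.72. The same window was at −0.4 in D4, −0.35 in G10 and −0.04 in G4. The windows of chromosome 3 that hold PIK3CA, SOX2 and TP63 were at −0.45 to −0.56 in D4, G10 and H3 and at −0.14 and −0.15 in G4. With window medians subtracted, an alternative chosen after seeing the data, 733 genes were shared by the 4 clones in place of 1186, and 527 of these were among the 1186.

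**Figure D5:**
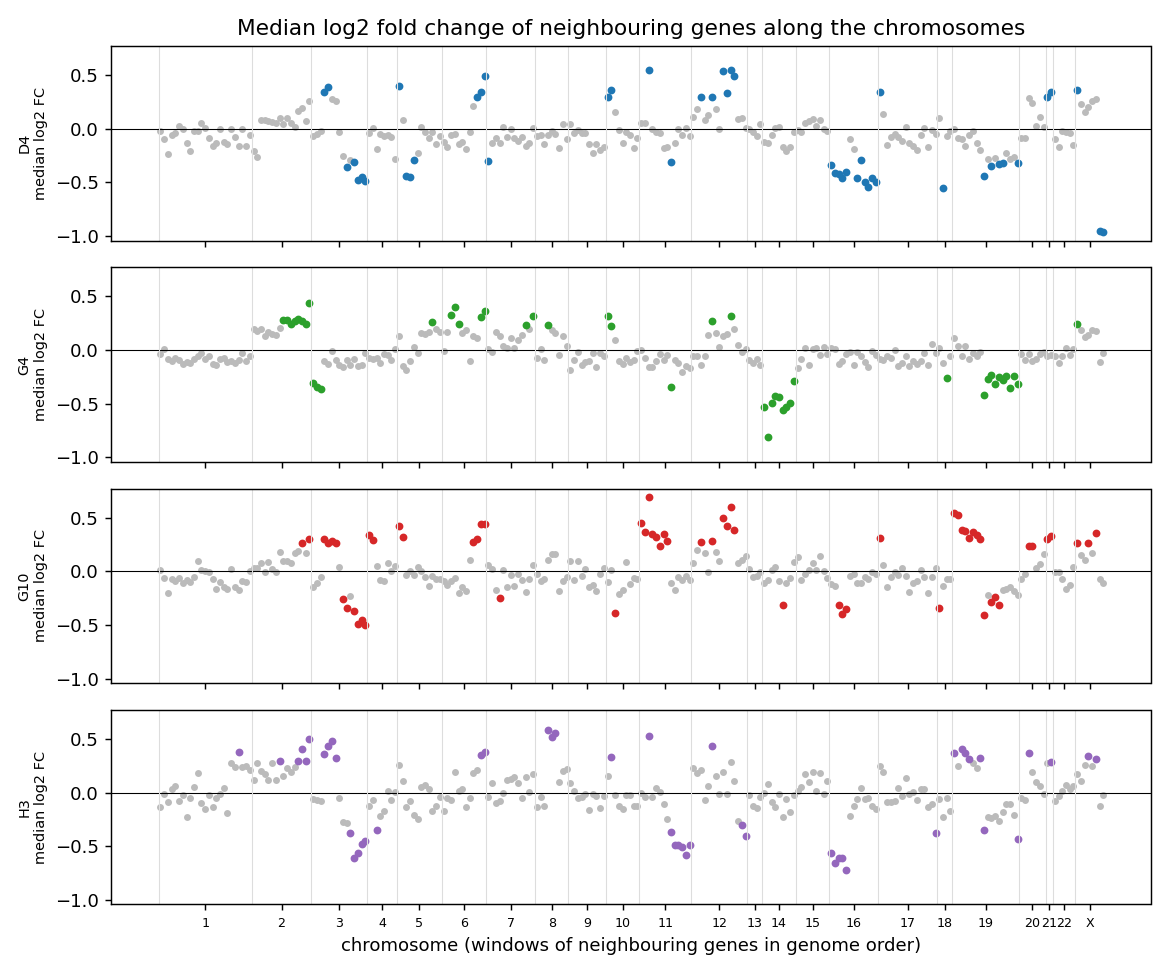
Median log2 fold change against the control (y axis) of windows of 50 neighbouring genes in genome order (x axis), 1 panel per clone. The genes of the windows had a mean of at least 5 CPM. Windows beyond the shuffled orders are in colour and the others in grey. Chromosome 14 has a median of −0.51 in G4, and the end of chromosome X lies at −0.96 in D4.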

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

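The tests of chance order along the chromosomes, of thinned depth, of mistaken libraries, of a share of control cells over 50% and of other references were chosen only after the result was seen. What drew attention was a difference between clones under the same contrast with the control, by the limma F test or by opposite calls.

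The 4 clones differed among themselves in 11889 genes, and 1576 genes were called in opposite directions against the control in at least 2 clones. All 24 named shared genes, although changed the same way in every clone, differed in size between clones. The adjusted p between clones was 1.46e-13 for INPPL1, 4.25e-09 for EGFR, 1.6e-09 for TP63, 1.36e-08 for SOX2, 1.52e-06 for PLK1, 0.000273 for PIK3CA and 0.000386 for AKT1. EGFR was lowest in H3 at 240.4 CPM, TP63 in G10 at 85.34 CPM, and PLK1 ranged from 132.64 CPM in D4 to 230.92 CPM in G4.

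Runs of neighbouring genes shifted together, some in 1 clone, such as chromosome 14 in G4 and the end of chromosome X in D4, and others in several, with 4 windows shifted the same way in all 4 clones. Chance order along the chromosomes is argued against by the 20.1% of window medians that lay beyond a bound from shuffled orders. The bound was the 95th percentile of the largest absolute window median in each shuffled order. A bias of GC content and transcript length is argued against as well, since 93.1% of the shifted windows were left after correcting for both. Medians of adjacent windows correlated at 0.75, against 0.08 at the 95th percentile of shuffled orders, which differences in copy number between the clones could give, but so could any other cause acting on long stretches. DNA was not analysed here, so both copy number and regional regulation of expression stay open, as does a state of the control colony for the windows shifted in all 4 clones, and no biological explanation was tested.

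Clone G4 lay closest to the control, with 4827 differing genes and with KRT6A, CPT1A, COL17A1 and SOX2 nearer to the control level than in the other clones. A swap with control libraries is argued against, since INPPL1 in G4 lay 14.5 standard errors below the control. Unequal depth as the whole cause is argued against, since control and G4 still differed in the fewest genes, 4528, when all libraries were thinned to the same number of reads (next D4 and G10 with 4898). An earlier test of similar depth was undecided, with D4 and G4, the pair closest in depth, differing in 1.45 times as many genes as control and G4. Control cells in the G4 cultures may contribute. Of the genes at 20 CPM or more in the control only 2, among them CHL1 (11.1%), lay below 20% of it. A share over 50% is argued against by 42 genes that lay below 50% by more than 2 standard errors. An incomplete effect of the edit in G4 stays open, untested. INPPL1 mRNA stood at 44.8% of the control in G4, below D4 (61%) and H3 (59.9%) and above G10 (6.55%). That level does not tell how much SHIP2 protein was left.

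The 1186 genes shared by the 4 clones may reflect the loss of SHIP2 or a peculiarity of the single control colony. Sampling noise with no difference between any groups is argued against, since the highest count in 50 such simulations was 1. These drew noise for each gene independently and held no differences between clones. They therefore do not tell how many genes noise in the 2 shared control libraries adds. A difference particular to the control colony stays open, as 1 other reference, H3, gave at least as many genes (2180). At least 2-fold, D4 (88) and H3 (155) gave more than the control (60), while G4 (49) and G10 (40) gave fewer. Clone-to-clone variation alone stays open too, and the simulations of it cannot decide. Of 100 simulations in which 5 clones differ at random, 55% gave as many genes (median 1593.5). The simulated clones were drawn with a larger variance than the 4 knock-out clones showed, which favours high counts. Shifted chromosome stretches could account for part, since 44.4% of the genes were kept after window medians were subtracted, against 81.8% to 84.7% with shuffled positions. Unlike the first, the shuffled runs left genes below a mean of 5 CPM unshifted and required the same direction. Part of the gap may therefore come from the procedure.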

How the results depend on the processing

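The subtraction of window medians was chosen after seeing the data, and the DESeq2 Wald test was not run because the deposited values were not counts. Under median-of-ratios size factors and limma-voom every named value kept its direction and its side of the threshold and every count stayed within 1.5 times; the gene lists were refitted with the size factors only, where all calls held. The size factors turned the excess of falls into one of rises for the mean of the clones (3543 up and 3470 down), for the genes shared by all 4 (621 and 579), for D4 and for G4. A minimum mean of 5 CPM changed no call among the genes it kept. With the clone as the unit of replication the 7105 genes changed in the mean of the clones became 0 from clone means by limma (693 at an unadjusted p under 0.05) and 16 with the clone as a random block. The cause is the construction, since these fits take the spread between clones as the error. In 2 groups with the clone ignored, where libraries count as replicates and the spread between clones also enters the error, there were 306. At an absolute log2 fold change of at least 1 there were 474, and 60 of the shared genes passed it in each clone. With window medians subtracted 733 genes were shared, AKT2 went from −0.23 to 0.049 and RPS2, which encodes a ribosomal protein, from −0.28 to 0.022. Of 190 named values the subtraction ended 16 calls beside those of AKT2 and RPS2, leaving out control replicate 1 ended 10 and control replicate 2 ended 6, leaving out any other single library ended 0, and no filter ended 1. Of the 166 named values for the mean of the clones, leaving out clone H3 ended 5 calls and clone D4 ended 2 beside that of FBLN1. The clone means ended 162, the random block 155 and the 2 groups 142. Leaving out 1 library or clone at a time gave 4503 to 7593 genes for the mean, and leaving out 1 library gave 2852 to 5389 for G4 and 702 to 1237 for all 4 clones. The lone library left in a group is then assumed to vary like the other groups. FBLN1, a fibroblast marker, had a log2 fold change of 0.23, which was −0.028 without clone D4 and 0.579 without clone G10. Of the gene list tests 20 passed with a preset correlation, 0 with an estimated correlation and 32 by fry. With an estimated correlation the adjusted p was 0.0624 for basal squamous, fatty acid, unfolded protein response and histone genes. It was 0.101 for antigen presentation, 0.106 for cholesterol, 0.173 for receptor tyrosine kinase, 0.207 for interferon, 0.208 for squamous differentiation and 0.237 for genes near INPPL1. It was 0.242 for ERK output, G2/M and fibroblast genes, 0.267 for matrix metalloproteinases and 0.359 for mesenchymal genes. It was 0.475 for oxidative phosphorylation and immediate early genes, 0.479 for G1/S and mitochondrially encoded genes and 0.604 for ribosomal protein genes. By fry, lists that camera did not call passed with an adjusted p of 0.000584 for junction, 0.000732 for p53, 0.00215 for columnar marker, 0.00541 for Notch and 0.0103 for both WNT and NF-kappaB genes. It was 0.0142 for endocytosis, 0.0153 for apoptosis, 0.0191 for NRF2, 0.0218 for YAP/TAZ and 0.0233 for TGF-beta genes. Hypoxia and glycolysis genes passed with the opposite sign (0.00451, median 0.01 and mean −0.01). Deviations of replicates with the same number correlated at 0.21 to 0.41 among the control, D4, G4 and G10 but at −0.08 to −0.24 with H3, and the labels name no shared batch, so the numbers were not taken to pair the libraries. With replicate as a block 7696 genes were called for the mean, the squamous differentiation list gave an adjusted p of 0.0542, as it gave 0.0558 with a pseudocount of 0.1, no other call changed and no count moved by over 1.5 times. Without a filter the fibroblast list gave 0.107. Leaving out 1 library moved the adjusted p from 0.0253 to 0.0717 for G1/S, 0.036 to 0.125 for columnar markers, 0.0221 to 0.0645 for fibroblast markers and 0.0154 to 0.0664 for immediate early genes. It ran from 0.036 to 0.0717 for matrix metalloproteinases, 0.0294 to 0.0523 for mesenchymal, 0.022 to 0.0664 for oxidative phosphorylation and 0.0294 to 0.0683 for squamous differentiation genes. Apart from the clone-level fits and the estimated correlation, the cause of these changes was not tested. Small changes are the least detectable at this depth and replication, as simulated 1.5-fold changes were recovered in all 4 clones for 17.9% of genes, against 89.6% at 2-fold.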

Other observations

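The 12 gene families examined here, some of whose members also stand in the lists above, and their tests were chosen after the values were seen. The 4 tested metallothionein genes, which bind zinc and copper, all rose over the clones with a median log2 fold change of 1.11, and being fewer than 5 genes they are given without a family test. MT1X rose from 7.44 CPM to 12.19 CPM in G4 and 32.61 CPM in D4. Of 8 clade B serpins, a group of protease inhibitors, 5 fell (median −0.77), among them SERPINB5 (−0.72), known as maspin. They are given without a family test, since SERPINB2, SERPINB10 and SERPINB13 had already been seen among the largest losses. The laminin chain genes LAMB3 and LAMA3, which serve the anchoring of squamous epithelium, fell in all 4 clones, LAMB3 from 952.9 CPM to 208.05 to 399.36 CPM and LAMA3 by a log2 fold change of −1.40. Laminin chains as a family did not pass (adjusted p = 0.274), with LAMA1 up and LAMB2, at 57.87 CPM in G4 and 253.52 CPM in H3, differing in direction between clones.

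Keratins went both ways, 6 up and 7 down of 20 (camera adjusted p = 0.572). KRT17, a keratin of stressed epithelium, fell from 436.46 CPM to 55.19 CPM in G10 and 44.09 CPM in H3 but only to 350.83 CPM in D4, while KRT80 rose from 102.01 CPM to 463.89 CPM in D4. Zinc finger genes with ZNF symbols fell in 120 of 404 and rose in 50 (median −0.13, camera adjusted p = 0.0335, or 0.429 with an estimated correlation). Window medians were not subtracted in the family tests, so falls that ZNF genes share with neighbouring genes were not separated. Of 11 MAGE genes 6 fell and 1 rose (camera adjusted p = 0.0676). The shift was largest in D4, where 8 fell and 1 rose (median −0.76). In H3 2 fell and 4 rose (median −0.13), and the median was −0.26 in G4 and −0.05 in G10. Aminoacyl-tRNA synthetase genes fell in 9 of 17 and rose in 3 (adjusted p = 0.0739), with AARS down by a log2 fold change of −0.60. Aldo-keto reductase genes had a median of 0.82 in G4 and −0.66 in G10 (adjusted p = 0.274 over the clones). S100 proteins (adjusted p = 0.25), protocadherins (0.451), claudins (0.707) and collagens (0.707) did not pass.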
